A study of Mus musculus with 6 samples.

How the data were processed

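RNA sequencing of 6 mouse samples was examined in 3 groups of n = 2: tumours from PANC02-H7 cells (H7), tumours from UN-KC-6141 cells (UNKC), both grown in the pancreas for 20 days, and normal whole pancreas. Per the labels, the authors aligned reads with STAR, counted them with featureCounts and tested them with DESeq2 1.18.1. As deposited by the authors, the counts of each sample are raw whole-number read counts per gene ID, for 27179 genes. The authors' 2 comparison tables, which cover genes with at least 10 counts over 4 libraries, hold counts and TPM, which the authors computed from those counts and the gene length in bases. The same tables hold the authors' log2 fold changes from DESeq2 and the authors' p-values with their adjusted p-values. Names came from those tables for 16265 gene IDs and from the RefSeq annotation for 9376, and 1538 stayed without a name. The per-sample counts held both mates of a read pair (median ratio to the fragment counts of the tables from 1.98 to 2.00), so small counts are less independent than they look. The strand of the libraries is not stated, and the labels do not say that replicate numbers pair samples, so they were treated as names only.

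Counts were analysed with edgeR 4.0.16 and limma 3.58.1 in R 4.3.3, and with DESeq2 1.42.0 as an alternative. Python 3.11.15 with pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9 prepared tables, gave counting intervals and drew figures. Genes passing filterByExpr (16306) were scaled with TMM factors and tested in 3 comparisons with the edgeR quasi-likelihood model (legacy = FALSE) fitted to all 6 libraries. Every adjusted p of a gene is from this edgeR model, unless DESeq2 or the authors' table is named, with the Benjamini-Hochberg correction over all tested genes and a threshold of 0.05. CPM are counts scaled to the effective library size, given as mean with SD, and log2 fold changes are given with the standard error of the fit. Where 1 group had no read, the fold is a lower bound against a floor of 3 read pairs over that group, or 6 read counts (1.41 CPM in normal pancreas, 0.0408 in H7 and 0.0342 in UNKC tumours). With 1 to 3 read pairs in a group, the fold has a 95% counting interval (exact binomial, on pairs, log2 scale where the fold is log2), and intervals and floors cover counting error only. The adjusted p of a list is from camera in limma on log2 CPM (prior count 2) with a preset correlation of 0.01, adjusted over the 40 lists; camera was also run with an estimated correlation. The fry test asks whether the genes of a list move on balance in 1 direction and does not compare the list with other genes. Of the genes in the lists, 2 matched no measured gene.

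The comparisons, the lists, the tests and 19 alternatives were chosen before the data were examined, and 6 alternatives were added after seeing the data. The 19 cover other scalings, filters and tests, each library left out in turn (the lone library of a group is assumed to vary like the other groups), a replicate block, an estimated correlation and fry. The added ones leave ribosomal RNA, Lars2 and 1 unnamed gene out of the library size, use the authors' fragment counts, remove the trend on gene length (loess, span 0.5), thin the tumours to the depth of the normal libraries, halve the read counts, and run camera on z-scores. Named genes are the 5 study genes, the 4 largest rises and 4 largest falls with at least 10 CPM in the higher group, and up to 2 rises and 2 falls per list with at least 5 CPM (for a list with none past the threshold, the member with the highest CPM); the text does not name them all. Kmt2a, Kmt2c, Kmt2d and Ncoa6, Smad4 and Mtap against normal pancreas, and members named without a fold change behind counts of 5 or fewer were chosen after their values were seen.

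Effective library sizes were set by TMM factors of 2.07 to 2.23 in the tumours and 0.179 and 0.256 in normal pancreas. Of the tested genes 15.1% and 16.8% had no read in the normal libraries and 0.521% to 2.05% in the tumours. The log2 CPM of replicates correlated across genes at r = 0.967 for H7, 0.949 for UNKC and 0.802 for normal pancreas, and genes are not independent replicates. The pipeline was tested on simulated data of 15481 genes with this depth. The simulation gave all groups the same spread, taken from its trend on expression. Real replicates of normal pancreas were less alike than those of the tumours, so the simulated rates may not hold against normal pancreas. Of genes changed 2-, 4- and 8-fold the pipeline recovered 3.19%, 37.5% and 57.3% in H7 tumours against normal pancreas and 3.55%, 38.3% and 66.3% in UNKC tumours. Between the tumours it recovered 22.9%, 79.2% and 92.2% of genes changed in H7 and 25.4%, 80.3% and 95.3% of those changed in UNKC. Of unchanged genes it called 1 of 14881, 1 of 14873 and 69 of 14301. A simulated list raised in H7 tumours was found by camera (adjusted p = 4.39e-12 against normal pancreas and 1.6e-30 against UNKC tumours) and missed with an estimated correlation (0.195 and 0.0502). Of 40 random lists fry called 23 and 21 against normal pancreas and camera 0. The simulated genes were drawn independently of each other. These lists therefore cannot show false calls of camera on correlated genes, nor decide between the preset and the estimated correlation.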

Results

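RNA was sequenced from 6 mouse samples in 3 groups of n = 2: whole pancreas of C57BL/6 mice, tumours grown from PANC02-H7 cells (H7 tumours) and tumours grown from UN-KC-6141 cells (UNKC tumours). Both lines are mouse pancreatic carcinoma lines, and the cells were injected into the pancreas of C57BL/6 mice whose tumours were taken 20 days later. The tumour libraries held 33332516 and 36307030 (H7) and 40507546 and 38728423 (UNKC) reads counted in genes. The normal pancreas libraries held 12077320 and 8204225. Ribosomal RNA took 86.3% and 85.1% of the reads of the normal libraries, against 27.8% and 24.6% in H7 and 21.2% and 20.1% in UNKC tumours. Without ribosomal RNA, Lars2 and 1 unnamed gene, which were abundant in the normal libraries, 780779 and 699044 reads were left in the normal libraries and 23880939 to 31828387 in the tumours. A tested gene had a median of 11 and 12 reads in the normal libraries and of 460 to 625.5 in the tumours. Skeletal muscle genes held 47978 reads in H7 replicate 2 and 186858 in UNKC replicate 2, against 732 and 148 in their replicates 1 and 16 and 6 in normal pancreas. The labels give 1 text on extraction and library for all samples and name no batch, so any difference in the making of the normal and tumour libraries coincides with every comparison against normal pancreas. The sex of the mice and the mouse of origin of each replicate are not stated. The p-values of genes rest on the spread between these samples, estimated over all 3 groups together. Replicates of normal pancreas were less alike (r = 0.802 across genes) than those of H7 (0.967) and UNKC tumours (0.949). A shared spread may therefore make p-values too small against normal pancreas and too large between the tumours. Fits of only the 4 libraries compared, which tested fewer genes, called 4015 genes higher and 3230 lower in H7 tumours than in normal pancreas. For UNKC tumours they called 3816 and 2925, and between the tumours 2318 and 2497. The p-values of lists from camera compare the listed genes with other genes and rest on the preset correlation between genes.

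**Figure D1:**
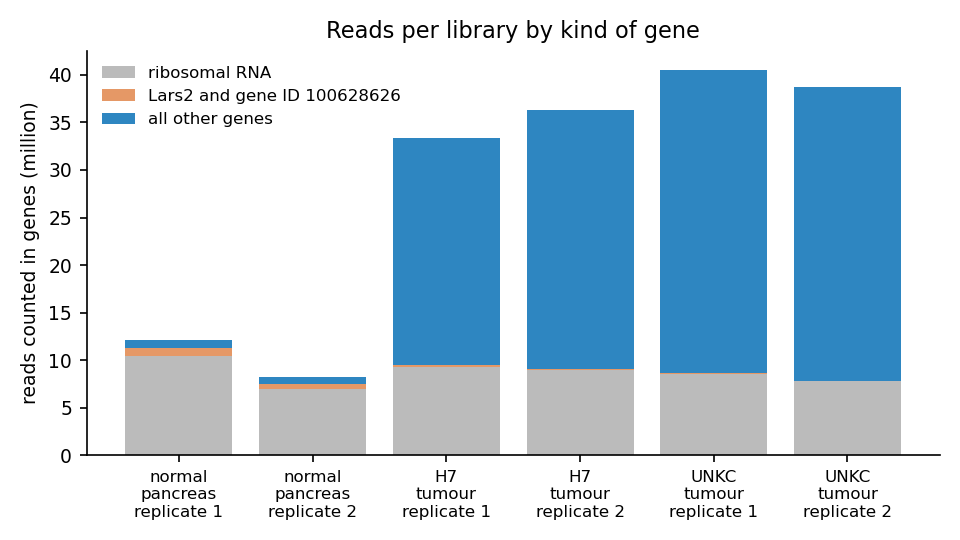
Reads counted in genes in each of the 6 libraries, split into ribosomal RNA (grey), Lars2 with 1 unnamed gene (orange) and all other genes (blue). In the normal pancreas libraries the blue part is 780779 and 699044 reads, a thin band at the top of each bar.

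H7 tumours were compared with normal pancreas to find the genes that change when the organ carries this tumour, as the design text of the series asks. In H7 tumours 25 of 25 acinar enzyme genes were lower, while 29 of 30 cell cycle genes, 14 of 23 matrix proteases and inhibitors, 15 of 18 class I genes and 15 of 20 genes of glycolysis and hypoxia were higher. No list call was left with an estimated correlation (smallest adjusted p = 0.463). Spp1, which encodes the secreted phosphoprotein osteopontin, stood at 1069 ± 64.5 CPM (reads scaled to the size of the library, SD, n = 2) in H7 tumours and 37.7 ± 12.8 in normal pancreas (log2 fold change 4.83 ± 0.32 SE, adjusted p = 0.000189). Its receptor gene Cd44 rose by a log2 fold change of 3.06 ± 0.14 (adjusted p = 0.000132). Cd274, which encodes the checkpoint ligand PD-L1, rose by 2.49 ± 0.32 (adjusted p = 0.00152), from 2.83 ± 1.39 to 15.8 ± 1.99 CPM. Pdcd1, which encodes the PD-L1 receptor PD-1, had no read in either normal library and was at least 1.28-fold higher in H7 tumours (adjusted p = 0.0389). The Pdcd1 call was lost with upper-quartile factors (adjusted p = 0.0559), without a filter (0.0576), against a fold of 2 (0.0695), in the fit of only 4 libraries (0.0714) and with the length trend removed (0.0711). Wdr5, a scaffold of the complexes that methylate histone H3 at lysine 4 (H3K4), did not pass the test (log2 fold change 0.88 ± 0.34, adjusted p = 0.0726), with 19.5 ± 0.838 against 10.6 ± 5.88 CPM. In the table deposited by the authors the log2 fold changes were 4.66, 2.82, 2.08, 1.08 and 0.68 for Spp1, Cd44, Cd274, Pdcd1 and Wdr5, and their adjusted p was 0.124 for Pdcd1 and 0.104 for Wdr5.

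Spp1 (gene ID 20750) lies on chromosome 5 from 104435111 to 104441053 of the mouse GRCm38 assembly. Cd44 (gene ID 12505) lies on chromosome 2 from 102811141 to 102901669, Cd274 (gene ID 60533) on chromosome 19 from 29362107 to 29388095, Pdcd1 (gene ID 18566) on chromosome 1 from 94038305 to 94052553, and Wdr5 (gene ID 140858) on chromosome 2 from 27515147 to 27536535. All counts are over whole genes.

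**Figure D2:**
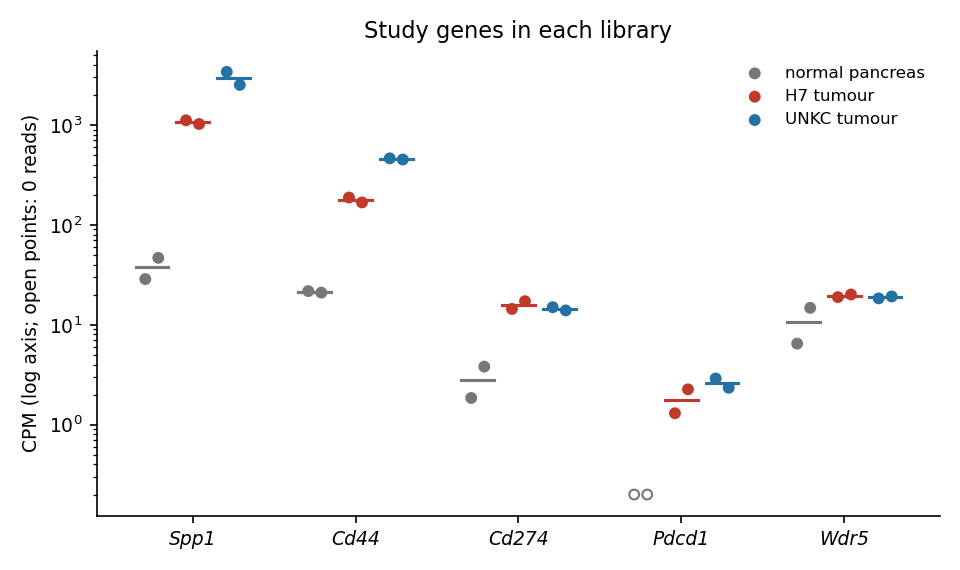
CPM (reads scaled to the size of the library) on a log axis for Spp1, Cd44, Cd274, Pdcd1 and Wdr5 in each of the 6 libraries (points) with the group mean (line, n = 2). Open points stand for 0 reads, drawn at the foot of the axis, and both normal pancreas libraries had 0 reads of Pdcd1.

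Of 16306 genes tested with edgeR, 4819 were higher and 3572 lower in H7 tumours and 7915 passed in neither direction. The authors' table listed 3536 higher and 3556 lower, and 3450 and 3192 genes were called in both. Among genes with at least 10 CPM, Adipoq, the fat cell hormone adiponectin, was at least 679-fold lower and Ces1e, a carboxylesterase, at least 529-fold lower, both with no read in H7 tumours. Tmed11, a cargo protein of the early secretory pathway, was at least 598.5-fold lower. From no read in normal pancreas, the long noncoding RNA Lncenc1 was at least 49.5-fold higher, and Edil3, an integrin-binding matrix protein, at least 30.7-fold higher. Tnfrsf12a, the receptor of the cytokine TWEAK, was at least 27.1-fold and Insc, an adaptor of spindle orientation, at least 26.5-fold higher.

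Normal tissue markers fell. All 25 measured genes of acinar cell enzymes fell (median log2 fold change -8.89, adjusted p = 2.51e-13 for the list), from -12.60 for Ctrc, a chymotrypsin, to -2.55 for Reg1. Amylase gene Amy2b went from 1120 ± 126 to 0.334 ± 0.0189 CPM (log2 fold change -11.70 ± 0.33). Of 7 acinar cell transcription factors 6 fell (adjusted p = 0.00055), among them Rbpjl at -10.66 ± 0.41 and Bhlha15, which drives secretory maturation, at -7.81 ± 0.49. Of 23 islet cell markers 17 fell (adjusted p = 0.000236), with the islet factor Nkx2-2 at -6.63 ± 0.63, while Pdx1 was among those that rose. Of 16 B cell and plasma cell markers 15 fell (adjusted p = 2.97e-05), including the B cell surface gene Ms4a1 with 2 reads in H7 tumours (1243-fold lower, counting interval 209 to 50440) and the antibody joining chain gene Jchain at -8.21 ± 0.43, while Sdc1 rose. Of 10 adipocyte markers 8 fell (adjusted p = 0.000548), as did 5 of 6 mesothelial markers (adjusted p = 0.0221; Upk3b, Upk1b, Lrrn4, Wt1 and Gpm6a, with Msln higher) and 3 of 4 red blood cell markers (adjusted p = 0.0483; Hba-a1, Hba-a2 and Alas2). With an estimated correlation these calls were lost, at adjusted p = 0.463 for the transcription factors, adjusted p = 0.505 for red blood cells and adjusted p = 0.49 for the others.

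Proliferation and matrix genes rose. Of 30 genes of cell cycle and proliferation 29 rose (median log2 fold change 3.20, adjusted p = 5.75e-06), with the mitotic kinase Cdk1 at 5.0 ± 0.27 (counting interval 3.20 to 7.03) and the cyclin Ccnb1 at 4.96 ± 0.73 (2.49 to 10.28). Of 18 mesenchymal transition genes 11 rose and 0 fell (adjusted p = 0.0211), with the matrix genes Tnc at 7.11 ± 0.36 and Fn1 at 5.25 ± 0.25. Of 23 matrix proteases and inhibitors 14 rose and Mmp19 fell (adjusted p = 0.0141), and the protease inhibitor Timp1 rose by 7.34 ± 0.66 (counting interval 4.86 to 12.64). Of 20 genes of glycolysis and hypoxia 15 rose and Pfkfb3 fell (adjusted p = 0.0108), with the hypoxia-induced carbonic anhydrase Car9 at 7.41 ± 0.93 (counting interval 3.90 to 11.69) and the glycolytic enzyme Eno1 at 4.49 ± 0.24. Of 19 target genes of the ERK pathway 15 rose (adjusted p = 0.00254), with the membrane protein gene Emp1 at 4.49 ± 0.28 and the growth factor Ereg at least 7.93-fold higher. Of 10 osteopontin receptors 7 rose (adjusted p = 0.02), with the integrin subunit Itgb5 at 3.86 ± 0.17, and 4 of the 5 study genes rose (adjusted p = 0.0211). The study genes come from the title of the series, which may rest on these samples, so their list is not independent evidence. Tested with an estimated correlation, these calls were lost, at adjusted p = 0.463 for cell cycle and ERK targets and adjusted p = 0.49 for the others.

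Immune genes moved in both directions. Of 18 genes of MHC class I presentation 15 rose (adjusted p = 0.00119), with the peptide loading gene Tapbp at 3.32 ± 0.20. Of 10 class II genes 8 rose and H2-Ob fell (adjusted p = 0.0183), with the protease Ctss at 4.20 ± 0.16 and the peptide exchange gene H2-DMb1 at 3.87 ± 0.26. Of 32 interferon response genes 20 rose and Ifih1 fell (adjusted p = 0.0107), with the chemokine Cxcl9 at 5.35 ± 0.77 and the GTPase Gbp2 at 4.31 ± 0.37. Of 32 inflammatory chemokines and cytokines 13 rose, and Tgfb2 and Vegfa fell (adjusted p = 0.0018), with the interleukin 1 antagonist Il1rn at least 14.0-fold higher. Of 24 checkpoint genes 12 rose and Cd200 fell (adjusted p = 0.0108), with Cd276, a B7 family ligand, at 4.31 ± 0.69 (counting interval 2.46 to 7.36) and the costimulatory receptor Tnfrsf9 at least 8.65-fold higher. Of 15 cytotoxic effector genes only Gzmb and Ccl5 rose, and the list call (adjusted p = 0.00642) rests on fitted values of genes absent from normal pancreas: its median was 6.97 as fitted and -0.86 with those genes at their bound. It was lost with camera on z-scores (adjusted p = 0.443). With an estimated correlation these calls were lost, at adjusted p = 0.511 for class I, adjusted p = 0.68 for interferon and adjusted p = 0.49 for the others. Of 23 macrophage and monocyte markers 15 rose and 3 fell without a list call (adjusted p = 0.0982), with the chemokine receptor Cx3cr1 at 4.76 ± 0.28 and the scavenger receptor Cd163 at -4.11 ± 0.35. With camera on z-scores this list was called higher (adjusted p = 0.00487), but not with an estimated correlation (0.547).

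Of 20 genes of oxidative phosphorylation 18 rose (adjusted p = 0.00055), with Cox6c, a subunit of cytochrome c oxidase, at 2.96 ± 0.21. Of 24 ribosomal protein genes 20 rose and Rpl5 fell (adjusted p = 0.000548), with Rpl18 at 3.51 ± 0.27. Both calls were lost with an estimated correlation (adjusted p = 0.49), and with the trend of fold change on gene length removed, an alternative chosen after the data were seen (adjusted p = 0.354 and 0.32), as were MHC class II presentation (adjusted p = 0.0644), mesothelial (adjusted p = 0.0823) and red blood cell markers (adjusted p = 0.112). Of 19 genes of H3K4 methyltransferase complexes 10 fell and 6 rose without a list call (adjusted p = 0.0789), with Cxxc1, which recruits the complexes to CpG islands, at -2.92 ± 0.15 and the methyltransferase Setd1b at -2.65 ± 0.26, and the median of -0.69 turned to 2.58 when scaled by total counts. That scaling moved the median of all genes to 3.61, so a list whose median turned upward under it did not rise against other genes. Of 22 genes of ER protein folding and secretion 11 rose and 7 fell (adjusted p = 0.791), with the acinar disulfide isomerase Pdia2 at -11.35 ± 0.37 and its relative Erp27 at -7.34 ± 0.41; the median was 0.47, the mean -0.54 and the test pointed down. Of 26 ductal and epithelial markers 9 fell and 5 rose (adjusted p = 0.0873), with the keratin Krt8 at 2.27 ± 0.26, and the median of -0.48 turned to 2.82 when scaled by total counts.

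The remaining lists were not called by camera. Of 22 fibroblast markers 7 rose and Cxcl12 and Clec3b fell (adjusted p = 0.64), and of 14 neutrophil markers 5 rose and Camp and Ngp fell (adjusted p = 0.525). Of 16 endothelial markers 6 fell (adjusted p = 0.072), and their median of -0.86 turned to 2.44 when scaled by total counts. Of 16 immediate early and heat shock genes 9 rose and Dusp1 fell (adjusted p = 0.108). Of 13 pancreatic cancer driver genes 6 rose and Smad4, Myc, Arid1a and Rnf43 fell (adjusted p = 0.829), and the median of -0.34 turned to 2.95 when scaled by total counts. Among T cell markers Cd8a rose and Cd28 and Il7r fell (adjusted p = 0.726), with a median of 0.34 while the test pointed down and -0.02 with upper-quartile factors. Of 5 H3K4 demethylases Kdm1a and Kdm5b rose and Kdm1b and Kdm5c fell (adjusted p = 0.726), with a median of 0.31, a mean of -0.11 and -0.05 with upper-quartile factors. Among dendritic cell markers Itgax, Irf8 and Fscn1 rose and Zbtb46 and Clec10a fell (adjusted p = 0.525), with a median of 1.22 as fitted and -0.45 with bounds. Among nerve and Schwann cell markers S100b rose and Mbp and Scn7a fell (adjusted p = 0.726; median -0.89, mean 1.10, and 2.44 when scaled by total counts). Among myofibroblast and pericyte markers Acta2 rose and Myh11 fell (adjusted p = 0.513), with a median of 0.17 while the test pointed down and -0.19 with upper-quartile factors. Kit and Tpsb2 of the mast cell and basophil markers fell (adjusted p = 0.435; median -2.12, and 1.14 when scaled by total counts). Of the 4 markers of liver and intestine Vil1 fell (adjusted p = 0.864; median 2.14 as fitted, -1.82 with bounds), and of the 4 sex-linked genes Xist, the RNA of the inactive X chromosome, fell, at -3.67 ± 0.20 (adjusted p = 0.22 for the list). The Xist call was lost when scaled by total counts (-0.39, adjusted p = 0.16), and the sex of the mice is not stated. The 9 skeletal muscle markers had 0 calls in edgeR (0 at an unadjusted p under 0.05, 2 higher in DESeq2, adjusted p = 0.726 for the list).

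Adjusted over the list alone, the counts of the 22 called lists were the same except 16 rises for ERK targets, 21 for interferon, 5 for the study genes and 0 for cytotoxic genes, and 2 falls for matrix proteases and 1 for mesenchymal genes. No list of the 40 was called with an estimated correlation (4 at an unadjusted p under 0.05), and fry called 29. Without normal replicate 1 the calls of MHC class II presentation (adjusted p = 0.0737), cytotoxic effector genes (adjusted p = 0.0565), interferon response (adjusted p = 0.131), matrix proteases and inhibitors (adjusted p = 0.0502), mesothelial markers (adjusted p = 0.0565) and study axis (adjusted p = 0.0565) were lost, without normal replicate 2 those of osteopontin receptors (adjusted p = 0.0928) and red blood cell markers (adjusted p = 0.206), and without H7 replicate 2 those of mesenchymal transition genes (adjusted p = 0.0549) and red blood cell markers (adjusted p = 0.0759). Calls were gained for endothelial markers without normal replicate 1 (adjusted p = 0.0463) or H7 replicate 2 (0.034), for ductal and macrophage markers without normal replicate 2 (0.0294) and for H3K4 methyltransferase complexes without H7 replicate 1 (0.0488). Pdcd1 lost its call without H7 replicate 2 or any normal or UNKC library (adjusted p up to 0.0843), and Wdr5 gained one without normal replicate 1 (log2 fold change 0.43, adjusted p = 0.041) and without normal replicate 2 (1.63, adjusted p = 0.00125), as well as in DESeq2 (0.74, adjusted p = 0.0147).

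UNKC tumours were compared with normal pancreas to ask the same question of a second tumour line. Here too 25 of 25 acinar enzyme genes were lower, and 28 of 30 cell cycle genes, 17 of 23 matrix proteases and inhibitors, 18 of 19 ERK target genes and 17 of 18 class I genes were higher. No list call was left with an estimated correlation (smallest adjusted p = 0.351). Spp1 rose by a log2 fold change of 6.30 ± 0.34 (adjusted p = 0.000149), to 2962 ± 623 CPM (SD, n = 2), and Cd44 by 4.42 ± 0.14 (adjusted p = 0.000101), to 458 ± 8.39 CPM. Cd274 rose by 2.36 ± 0.32 (adjusted p = 0.00198), to 14.5 ± 0.759 CPM, and Pdcd1 was at least 1.87-fold higher (adjusted p = 0.0248). Wdr5 did not pass the test (0.83 ± 0.34, adjusted p = 0.0914). The authors' table gave 6.09, 4.17, 1.94, 2.16 and 0.61 for Spp1, Cd44, Cd274, Pdcd1 and Wdr5, with an adjusted p of 0.0388 for Pdcd1 and 0.121 for Wdr5.

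In this comparison 4738 genes were higher and 3150 lower, and 8418 passed in neither direction. The authors' table listed 3595 higher and 3535 lower, and 3483 and 2952 genes were called in both. Hmga2, a chromatin protein of embryonic and tumour cells, was at least 88.7-fold higher from no read in normal pancreas, and Tnfrsf12a at least 35.3-fold. Hhip, which binds and inhibits hedgehog ligands, was at least 32.3-fold and Acsbg1, an acyl-CoA synthetase, at least 28.2-fold higher. The amylase gene Amy2a1, with no read in UNKC tumours, was at least 853-fold lower, Crb1, a cell polarity gene, at least 757-fold and Tmed11 at least 715-fold.

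All 25 genes of acinar cell enzymes fell (median log2 fold change -10.49, adjusted p = 1.93e-16), with Amy2b at -13.17 ± 0.35 and Ctrc at -13.01 ± 1.11. Of 7 acinar cell transcription factors 6 fell (adjusted p = 0.000483), with Rbpjl at -12.17 ± 0.43 and Bhlha15 at -7.81 ± 0.49, while Gata6 rose by 1.29 ± 0.37. Without either H7 or either UNKC library the Gata6 call was lost (adjusted p up to 0.0808). It was also lost with RLE factors (adjusted p = 0.0648), upper-quartile factors (0.0951), the stricter filter (0.0668), the fit of only 4 libraries (0.086), a test against a fold of 2 (0.231), the length trend removed (0.0786) and the tumours thinned (0.336). Of 23 islet cell markers 16 fell (adjusted p = 0.00011), with Nkx2-2 at -6.21 ± 0.60, and Pdx1 was among those that rose. Of 16 B cell and plasma cell markers 11 fell (adjusted p = 0.00022), with Ms4a1 at -4.94 ± 0.72 and the antibody heavy chain gene Ighm at -4.78 ± 0.76, and Sdc1 rose. The calls of Ms4a1 and Ighm were lost when scaled by total counts (-1.61, adjusted p = 0.079, and -1.45, adjusted p = 0.097). Of 10 adipocyte markers 7 fell and Pparg rose (adjusted p = 0.000797). Tested with an estimated correlation, these calls were lost, at adjusted p = 0.351 for the acinar lists, adjusted p = 0.425 for B cells and adjusted p = 0.483 for islets and adipocytes.

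Of 30 genes of cell cycle and proliferation 28 rose (median log2 fold change 2.73, adjusted p = 2.19e-05), with Cdk1 at 4.86 ± 0.27 (counting interval 3.05 to 6.88) and Ccnb1 at 4.67 ± 0.74 (2.19 to 9.98). Of 19 ERK pathway target genes 18 rose (adjusted p = 0.00022), with the growth factor Hbegf at 5.98 ± 0.40 (counting interval 4.44 to 8.27) and Ereg at least 5.69-fold higher. Of 18 mesenchymal transition genes 15 rose (adjusted p = 0.00023), with Tnc at 5.91 ± 0.35 and the calcium-binding gene S100a4 at 5.10 ± 0.19. Of 23 matrix proteases and inhibitors 17 rose (adjusted p = 0.00011), with Timp1 at 7.19 ± 0.66 (counting interval 4.72 to 12.50) and the macrophage elastase Mmp12 at least 14.0-fold higher. Of 20 genes of glycolysis and hypoxia 17 rose and Pfkfb3 fell (adjusted p = 0.00336), with Car9 at 6.88 ± 0.95 (counting interval 3.42 to 11.21) and the hypoxia-induced hydroxylase Egln3 at 4.70 ± 0.59. With an estimated correlation these calls were lost, at adjusted p = 0.483 for glycolysis and hypoxia and adjusted p = 0.351 for the others.

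Of 18 MHC class I genes 17 rose (adjusted p = 0.00023), with the immunoproteasome subunit Psmb8 at 3.65 ± 0.53 and the peptide transporter Tap1 at 3.18 ± 0.27. Of 10 class II genes 8 rose and H2-Ob fell (adjusted p = 0.0195), with H2-DMb1 at 4.14 ± 0.26 and Ctss at 3.07 ± 0.15. Of 32 inflammatory chemokines and cytokines 15 rose and Vegfa fell (adjusted p = 0.00011), with Il1rn at least 23.4-fold and the monocyte chemokine Ccl8 at least 12.8-fold higher. Of 24 checkpoint genes 14 rose and Entpd1 fell (adjusted p = 0.00343), with Cd276 at 4.97 ± 0.67 (counting interval 3.12 to 8.02) and Tnfrsf9 at least 8.04-fold higher. Of 15 cytotoxic effector genes 3 rose (adjusted p = 0.00184), the granule protease Gzmb at least 4.58-fold, the chemokine Ccl5 at least 5.75-fold, and Prf1, with a list median of 8.07 as fitted and 0.14 with bounds. This list call too rests on fitted values of absent genes and was lost with camera on z-scores (adjusted p = 0.149). Among T cell markers Cd8a rose by 3.24 ± 0.51 (counting interval 1.38 to 6.29) and Cd3d rose, while Il7r fell (19 tested, adjusted p = 0.538 for the list). Of 23 macrophage and monocyte markers 13 rose and Mertk and Cd163 fell without a list call (adjusted p = 0.0619), with the lipopolysaccharide coreceptor Cd14 at 5.02 ± 0.32 (counting interval 3.48 to 7.30) and the arginine-degrading enzyme Arg1 at 4.44 ± 0.54. With camera on z-scores this list was called higher (adjusted p = 0.00584), but not with an estimated correlation (0.517). Of 22 fibroblast markers 10 rose and Clec3b fell (adjusted p = 0.261), with the collagen gene Col1a1 at 4.48 ± 0.60. Tested with an estimated correlation, the calls were lost, at adjusted p = 0.351 for chemokines and checkpoints and adjusted p = 0.483 for classes I and II and cytotoxic genes.

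Of 20 genes of oxidative phosphorylation 17 rose (adjusted p = 0.000668), with Cox6c at 2.51 ± 0.21, and of 24 ribosomal protein genes 18 rose and Rpl5 fell (adjusted p = 0.00482), with Rpl18 at 3.29 ± 0.27. Of 19 genes of H3K4 methyltransferase complexes 9 fell and Ash2l, Dpy30, Hcfc1 and Wdr82 rose (adjusted p = 0.0208), with Setd1b at -3.36 ± 0.26 and Cxxc1 at -2.79 ± 0.15, and the median of -0.86 turned to 2.61 when scaled by total counts. That scaling moved the median of all genes to 3.77, above each list median that turned upward under it. Of 16 immediate early and heat shock genes 8 rose (adjusted p = 0.0412). With the gene length trend removed the calls of oxidative phosphorylation (adjusted p = 0.373), ribosomal proteins (adjusted p = 0.724), H3K4 methyltransferase complexes (adjusted p = 0.37), immediate early and heat shock genes (adjusted p = 0.338) and MHC class II presentation (adjusted p = 0.12) were lost. With an estimated correlation they were lost too, at adjusted p = 0.396 for immediate early genes and adjusted p = 0.483 for the others, as was the list of study genes (4 of 5 rose, adjusted p = 0.0191, and adjusted p = 0.425 with an estimated correlation). Of 10 osteopontin receptors 7 rose and Itga4 and Itga8 fell (adjusted p = 0.0825), with the integrin subunit Itgav at 3.34 ± 0.15. Of 22 genes of ER protein folding and secretion 8 fell and 7 rose (adjusted p = 0.377), with Pdia2 at -10.79 ± 0.36 and Erp27 at -9.19 ± 0.45; the median was 0.23, the mean -0.86, and the median -0.13 with upper-quartile factors. Of 26 ductal and epithelial markers 8 rose and 7 fell (adjusted p = 0.538), with Krt8 at 3.16 ± 0.26; the median was -0.17, the mean 0.20, and the median 3.22 when scaled by total counts.

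**Figure D3:**
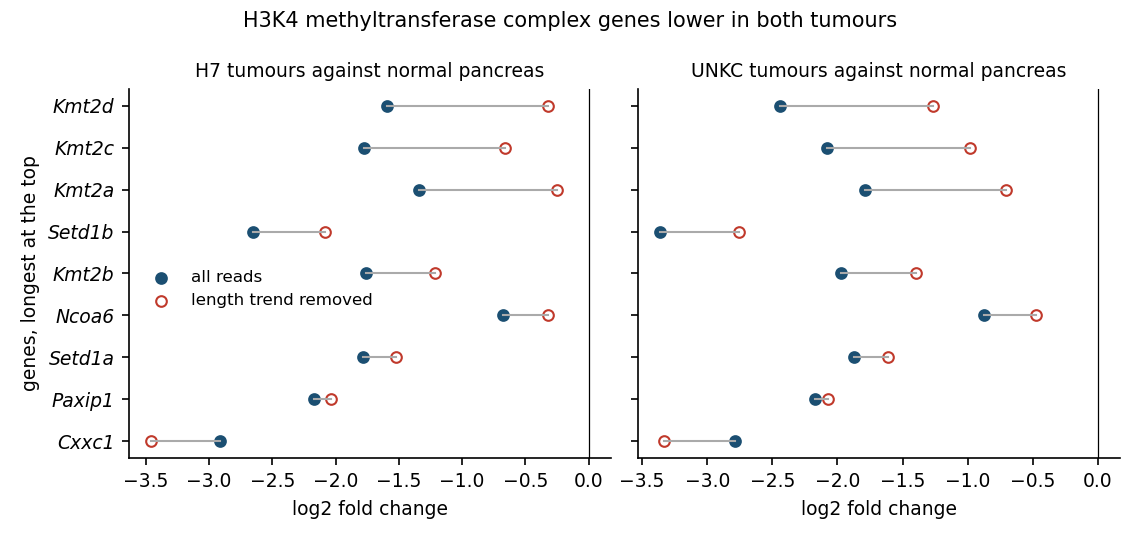
Log2 fold changes of the 9 genes of H3K4 methyltransferase complexes that were lower in both tumours than in normal pancreas, with all reads (filled) and with the gene length trend removed (open). When scaled by total counts the median of the whole list, not of these 9, was 2.58 in H7 and 2.61 in UNKC tumours. The median of all genes was then 3.61 and 3.77. Of the 9, Cxxc1 then stood at 0.38 in H7 and 0.58 in UNKC tumours and Setd1b at 0.65 and 0.021.

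Further lists were not called by camera in this comparison. Of 32 interferon response genes 14 rose and Stat2, Oas2 and Mx2 fell (adjusted p = 0.321). Of 13 pancreatic cancer driver genes 8 rose, with Mtap at 6.06 ± 0.30, and Myc, Arid1a and Rnf43 fell (adjusted p = 0.557). Of endothelial markers Flt1 and Cldn5 rose and Egfl7 fell (adjusted p = 0.793; median -0.01, mean 0.79, and 3.32 when scaled by total counts). Of neutrophil markers Mmp9, Il1b and Trem1 rose and S100a9, Camp and Ngp fell (adjusted p = 0.793; median -0.24, mean 0.90, and 3.07 when scaled by total counts). Of dendritic cell markers Itgax, Irf8 and Fscn1 rose and Zbtb46 and Clec10a fell (adjusted p = 0.538; median 1.07 as fitted, -0.03 with bounds). Of myofibroblast and pericyte markers Acta2 and Rgs5 rose and Myh11 and Notch3 fell (adjusted p = 0.896; median 0.68, with the test pointing down). Of mast cell and basophil markers Mcpt4 and Mcpt8 rose and Kit fell (adjusted p = 0.857). Of mesothelial markers Msln rose and Upk3b and Upk1b fell (adjusted p = 0.188; median -1.84, and 1.53 when scaled by total counts). Of H3K4 demethylases Kdm1a and Kdm5a rose and Kdm1b and Kdm5c fell (adjusted p = 0.793; median 0.38, mean -0.02). Mbp fell among nerve and Schwann cell markers (adjusted p = 0.857; median 1.84, with the test pointing down), Ttr among markers of liver and intestine (adjusted p = 0.793; median 2.92 as fitted, -2.72 with bounds) and Xist, at -3.60 ± 0.20, among sex-linked genes (adjusted p = 0.857; median 7.22 as fitted, 0.98 with bounds). The Xist call was lost when scaled by total counts (-0.24, adjusted p = 0.353). In edgeR 0 of the 4 red blood cell markers were called (1 at an unadjusted p under 0.05, 2 lower in DESeq2, adjusted p = 0.261 for the list; median -1.44, and 1.89 when scaled by total counts). The 9 skeletal muscle markers also had 0 calls (1 at an unadjusted p under 0.05, 7 higher in DESeq2, adjusted p = 0.793 for the list).

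Adjusted over the list alone, the counts of the 20 called lists were the same except 29 rises for cell cycle, 19 for oxidative phosphorylation, 19 for ribosomal proteins and 2 for cytotoxic genes, and falls of 18 for islets, 13 for B cells, 9 for adipocytes, 10 for H3K4 complexes, 2 for checkpoints and 2 for ribosomal proteins. No list was called with an estimated correlation (4 at an unadjusted p under 0.05), and fry called 29. Without normal replicate 1 the calls of H3K4 methyltransferase complexes (adjusted p = 0.121), MHC class II presentation (adjusted p = 0.086), immediate early and heat shock genes (adjusted p = 0.086), ribosomal proteins (adjusted p = 0.0599) and study axis (adjusted p = 0.0626) were lost. Calls were gained for macrophage and monocyte markers without normal replicate 2 (adjusted p = 0.00867), for red blood cell markers without UNKC replicate 1 (0.0479), and for mesothelial markers without H7 replicate 1 (0.0309), H7 replicate 2 (0.0133) or UNKC replicate 2 (0.05). With the gene length trend removed osteopontin receptors (0.000941) and ER protein folding and secretion (0.0137) were gained. Pdcd1 lost its call without UNKC replicate 1 (adjusted p = 0.0689) or 2 (adjusted p = 0.0589), and Wdr5 gained one without normal replicate 2 (log2 fold change 1.57, adjusted p = 0.00143) and in DESeq2 (0.64, adjusted p = 0.0366).

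**Figure D4:**
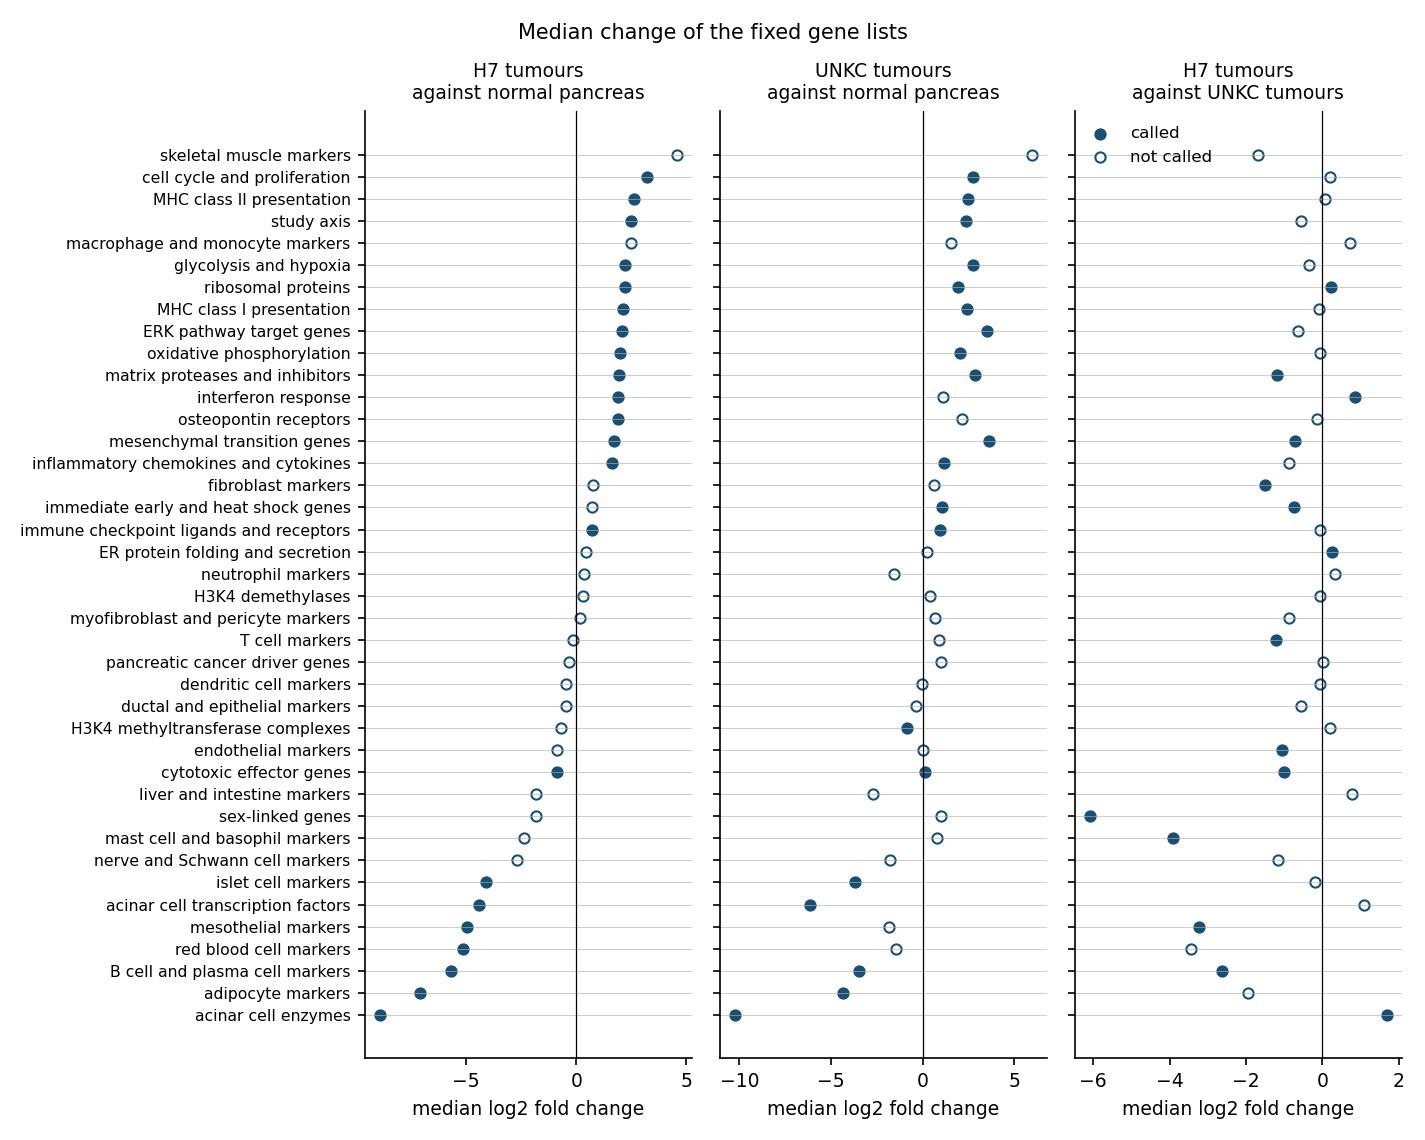
Median log2 fold change of each of the 40 gene lists in the 3 comparisons, with genes absent from a group set at their bound; filled points were called by camera with a preset correlation. Medians against normal pancreas shift when scaled by total counts, which moves the median of all genes to 3.61 and 3.77, and all calls were lost with an estimated correlation.

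The tumours had calls in common against normal pancreas. Of the genes higher, 3976 were called in both comparisons (1400.2 for independent lists), and of those lower 2648 (690.04 for independent lists). Across the 16306 genes, which are not independent replicates, the log2 fold changes had Pearson r = 0.891 and Spearman rho = 0.872. Both comparisons use the same 2 normal libraries, and in 20 simulations without any change this sharing alone gave a mean r = 0.971 and rho = 0.814, so r cannot show likeness of the tumours. The covariance was 8.92 against 5.15 in the simulations, the same sign was seen in 87.9% of genes against 79.4%. The simulations, which hold no effects, gave 0 shared calls in edgeR, and the independent lists leave out the shared controls. Part of the overlap may come from the shared controls, so its excess over either value does not measure a shared effect.

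The 2 tumours were then compared directly, which tests whether their changes against normal pancreas differ. UNKC tumours held more of Spp1 and Cd44 and of some mesothelial, endothelial, B cell and matrix protease genes, and H7 tumours more of some interferon response genes and acinar enzymes. No list call was left with an estimated correlation. Spp1 was lower in H7 tumours by a log2 fold change of -1.47 ± 0.27 (adjusted p = 0.0166) and Cd44 by -1.36 ± 0.12 (adjusted p = 0.00194). The Spp1 call was lost in 3 of 6 fits with a library left out (adjusted p up to 0.138), when scaled by total counts (0.0886) and against a fold of 2 (0.172). No difference was detected for Cd274 (0.13 ± 0.23, adjusted p = 0.76), Pdcd1 (-0.55 ± 0.39, adjusted p = 0.419) or Wdr5 (0.05 ± 0.29, adjusted p = 0.929).

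In H7 tumours 1152 genes were higher and 1808 lower than in UNKC tumours, and 13346 passed in neither direction. Higher in H7 tumours were Grpr, the receptor of gastrin-releasing peptide (log2 fold change 9.65 ± 0.38, counting interval 7.92 to 12.82), Lncenc1 (9.54 ± 0.71), the neutrophil chemokine Cxcl15 (7.92 ± 0.55) and the flavin monooxygenase Fmo1 (7.56 ± 0.62). Lower were the secreted protein Crisp1 (-11.52 ± 0.41) and Hhip (-9.34 ± 0.27). The choline transporter Slc5a7 had 1 read in H7 tumours (2525-fold lower, counting interval 453 to 99780) and the kelch protein Klhl1 had 2 (2397-fold lower, counting interval 430 to 94720). Smad4, Rnf43 and Mtap were among the pancreatic cancer driver genes that were lower (adjusted p = 0.586 for the list). Mtap, a purine salvage enzyme, stood at 3.16 ± 0.886 CPM against 266 ± 11 (-6.39 ± 0.27, adjusted p = 0.000335), and Smad4, which carries TGF-beta signals, at 13.3 ± 0.905 against 60.8 ± 2.78 (-2.19 ± 0.14, adjusted p = 0.000877). Mtap lies on chromosome 4 from 89137370 to 89181090 and Smad4 on chromosome 18 from 73634790 to 73703791.

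Epithelial and mesenchymal identity genes differed. Gata6, a factor of the classical epithelial state, was lower in H7 tumours (-4.37 ± 0.38), and of the acinar cell transcription factors Foxp2 (5.58 ± 0.71) and Rbpjl were higher (adjusted p = 0.342 for the list). Of 26 ductal and epithelial markers 9 were lower and Tff1 higher (adjusted p = 0.059), with the keratin Krt7 at -2.74 ± 0.28. Of 18 mesenchymal transition genes 9 were lower and Zeb2, Snai1 and Tnc higher (adjusted p = 0.0454), with Twist1 at -5.73 ± 0.54, the cadherin Cdh2 at -3.79 ± 0.22, Snai1 at 2.33 ± 0.51 and Tnc at 1.20 ± 0.27. The Tnc call was lost when scaled by total counts (adjusted p = 0.136) and against a fold of 2 (0.513), and that of Snai1 against a fold of 2 (0.0933). Of 22 fibroblast markers Pdpn, Thy1 and Cxcl12 were lower and Dcn, Pdgfra and Pdgfrb higher (adjusted p = 0.0453), with the growth factor receptor Pdgfrb at 2.41 ± 0.27. Of 12 myofibroblast and pericyte markers 4 were lower and the smooth muscle actin gene Acta2 higher, at 2.35 ± 0.32 (adjusted p = 0.586). Endothelial Cdh5, Flt1 and Cldn5 were lower (16 tested, adjusted p = 0.00557), with Flt1, a receptor of VEGF, at -2.63 ± 0.21. Of 6 mesothelial markers 5 were lower (adjusted p = 0.00461). Of 23 matrix proteases and inhibitors 10 were lower (adjusted p = 0.000429), with the protease inhibitor Timp3 at -3.01 ± 0.52. All calls of lists were lost with an estimated correlation, at adjusted p = 0.701 for fibroblast markers and adjusted p = 0.644 for the others in this paragraph.

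Immune genes also differed. Of 32 interferon response genes 7 were higher in H7 tumours and Cxcl11, Iigp1 and Ifih1 lower (adjusted p = 0.00461, and adjusted p = 0.701 with an estimated correlation), with the ubiquitin-like gene Isg15 at 2.47 ± 0.43. Of 32 chemokines and cytokines 10 were lower and 5 higher (adjusted p = 0.138), with the neutrophil chemokine Cxcl3 at 5.44 ± 0.31 and Ccl6 at -2.91 ± 0.28. Of 23 macrophage markers 5 were lower and 4 higher (adjusted p = 0.557), with Arg1 at -4.64 ± 0.45 and Cx3cr1 at 2.29 ± 0.20, and of 14 neutrophil markers 4 were higher and Ngp lower (adjusted p = 0.166), with the receptor Csf3r at 2.40 ± 0.23. Lower were 6 of 16 B cell and plasma cell markers (adjusted p = 0.000696), the T cell markers Cd8a, Cd5 and Trbc2 (19 tested, adjusted p = 0.0162), the cytotoxic gene Ccl5 at -2.57 ± 0.28 (15 tested, adjusted p = 0.0383) and 6 of 9 mast cell and basophil markers, with Hdc higher (adjusted p = 0.0453). Tested with an estimated correlation, these 4 calls were lost, each at adjusted p = 0.644.

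Of 25 acinar cell enzymes 10 were higher in H7 tumours (median log2 fold change 1.8, adjusted p = 1.9e-07), with the carboxypeptidase Cpa1 at 2.54 ± 0.58 from 6.4 ± 1.30 against 1.10 ± 0.923 CPM, both far below the 1968 ± 55.8 of normal pancreas. The Cpa1 call was lost in the fit of only the 4 tumour libraries (adjusted p = 0.054) and against a fold of 2 (0.104). Higher too were 4 of 22 genes of ER protein folding and secretion (Pdia6, Sel1l, Creld2 and Erp27, adjusted p = 0.0383) and of 24 ribosomal protein genes Rpl7 and Rps6, the latter by 1.85 ± 0.22 (adjusted p = 0.0281). Of 16 immediate early and heat shock genes Fos, Jun, Junb, Hspa1a and Hspb1 were lower and Nr4a1 higher (adjusted p = 0.0399), with the small heat shock gene Hspb1 at -4.63 ± 0.48. Of 4 sex-linked genes Ddx3y was lower (adjusted p = 0.0399), from reads in UNKC tumours, with the sex of the mice not stated. With an estimated correlation these 5 calls were lost, each at adjusted p = 0.644. Of 19 ERK target genes 9 were lower and Spry1 higher (adjusted p = 0.122), with the phosphatase Dusp4 at -2.66 ± 0.29. The median of H3K4 methyltransferase complexes was 0.20 (1 of 19 higher, Psip1, adjusted p = 0.114), and 0 of 30 cell cycle genes were called in edgeR (4 at an unadjusted p under 0.05, 7 higher in DESeq2, adjusted p = 0.169 for the list).

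The other lists were not called by camera. Of checkpoint genes Vsir and Entpd1 were higher and Pdcd1lg2, Nectin2 and Nt5e lower (24 tested, adjusted p = 0.619), and of osteopontin receptors Itga4 and Itga8 were higher and Cd44, Itgav, Itgb1 and Itga5 lower (10 tested, adjusted p = 0.734). Of MHC class I genes Tapbp and Calr were higher and H2-Q4, H2-Q6 and H2-Q7 lower (adjusted p = 0.99), and of class II genes Ctss was higher (adjusted p = 0.715; median 0.07, and -0.01 when scaled by total counts). Of the genes of glycolysis and hypoxia Slc2a1, Hk2, Slc16a3 and Egln3 were lower (adjusted p = 0.102), of the adipocyte markers Fabp4 and Pparg (adjusted p = 0.0724) and of the red blood cell markers Hba-a2 and Slc4a1 (adjusted p = 0.056). Ndufa4 of oxidative phosphorylation (adjusted p = 0.759; median -0.05, mean 0.02) and Itgax of the dendritic cell markers (adjusted p = 0.867; median -0.06, mean 0.06) were higher. S100b was higher and Uchl1 lower among nerve and Schwann cell markers (adjusted p = 0.724), and Vil1 was lower among markers of liver and intestine (adjusted p = 0.557). The 5 study genes had Spp1 and Cd44 lower (adjusted p = 0.129), and islet (adjusted p = 0.99), skeletal muscle (adjusted p = 0.99) and H3K4 demethylase genes (adjusted p = 0.759) had 0 calls in edgeR. At an unadjusted p under 0.05 there were 1, 0 and 1, and DESeq2 called 1 islet gene higher and 1 lower, 0 muscle genes and 1 demethylase lower.

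Adjusted over the list alone, 15 acinar enzymes, 13 interferon genes, 2 immediate early genes, 4 mesenchymal genes and 1 ribosomal protein gene were higher, and lower were 14 matrix proteases, 7 B cell, 6 mesothelial, 2 T cell, 9 fibroblast, 8 immediate early, 11 mesenchymal and 3 sex-linked genes, with the other counts of the 15 called lists the same. No list was called with an estimated correlation (0 at an unadjusted p under 0.05), and fry called 3. The counts of 1152 and 1808 genes went to 184 and 378 without H7 replicate 1, 406 and 754 without H7 replicate 2, 376 and 956 without UNKC replicate 1, 552 and 1172 without UNKC replicate 2, 2159 and 2456 without normal replicate 1, and 2165 and 2449 without normal replicate 2.

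Of the 34 genes named and called in the comparison of the tumours, 22 kept their call in each of the 6 fits that leave out 1 library. Spp1 lost its call without H7 replicate 1 (adjusted p = 0.138), H7 replicate 2 (adjusted p = 0.12) or UNKC replicate 1 (adjusted p = 0.0776), and Tnc and Snai1 without the same libraries (adjusted p up to 0.184 and up to 0.203). Isg15 and Cpa1 lost theirs without either H7 library (adjusted p up to 0.0894 and up to 0.151), and Cpa1 also without either normal library (adjusted p = 0.0552 and 0.0559). Arg1, Ccl5, Acta2, Timp3, Dusp4, Hspb1 and Rps6 lost theirs without H7 replicate 1 (adjusted p of 0.0539 to 0.0893), and Isg15 and Hspb1 also with the tumours thinned (0.0653 and 0.05002). Among the lists, fibroblast markers (adjusted p up to 0.292) and mesenchymal transition genes (up to 0.0807) were lost without UNKC replicate 2 or either normal library, and fibroblast markers also without H7 replicate 1 (0.12) and with camera on z-scores (0.0692). Interferon response (adjusted p = 0.13), ER protein folding and secretion (0.116), immediate early and heat shock genes (0.0795) and sex-linked genes (0.127) were lost without H7 replicate 2. Sex-linked genes were lost without normal replicate 1 (0.0788) or 2 (0.0787), cytotoxic effector genes without H7 replicate 1 (0.12), immediate early and heat shock genes without UNKC replicate 1 (0.0617), and ER protein folding and secretion (0.0807) and ribosomal proteins (0.253) without UNKC replicate 2. Calls were gained for ERK targets and cell cycle without either normal library (adjusted p up to 0.0069 and up to 0.0208) and for ductal markers without UNKC replicate 2 (0.00317) or H7 replicate 1 (0.0381), among others. With the gene length trend removed the calls of mesenchymal (adjusted p = 0.0502), fibroblast (0.0565), mast cell (0.0618), ribosomal protein (0.09) and immediate early genes (0.0502) were lost.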

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

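Of the tests below, those of genomic DNA, macrophages, epithelial cells and overlapping genes, and the alternatives that thin the tumours, remove the length trend or use fragment counts, were chosen only after the result was seen.

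The changes of H7 and UNKC tumours against normal pancreas differed when tested directly, H7 minus UNKC, in edgeR. The change was higher in H7 tumours for 1152 genes and lower for 1808, and without H7 replicate 1 these counts were 184 and 378, without H7 replicate 2 406 and 754, without UNKC replicate 1 376 and 956, without UNKC replicate 2 552 and 1172, and without normal replicate 1 or 2 2159 and 2456 or 2165 and 2449. Calls against normal pancreas had opposite directions for 26 genes higher in H7 and lower in UNKC tumours, and for 107 the other way. By camera 4 lists were higher in H7 tumours and 11 lower, none of them with an estimated correlation. Among genes, the difference was -1.47 for Spp1, -1.36 for Cd44, 1.20 for Tnc, -2.19 for Smad4 and -6.39 for Mtap. Spp1 lost its call without H7 replicate 1, H7 replicate 2 or UNKC replicate 1 (adjusted p = 0.138, 0.12 and 0.0776), as did Tnc (0.184, 0.105 and 0.134).

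Of the genes of H3K4 methyltransferase complexes 9 were lower in both tumours than in normal pancreas (Kmt2a, Kmt2b, Kmt2c, Kmt2d, Setd1a, Setd1b, Ncoa6, Paxip1 and Cxxc1; medians -1.77 and -2.08). When scaled by total counts the median of the whole list, not of these 9, turned to 2.58 and 2.61. It stayed below the median of all genes (3.61 and 3.77). Many of the 9 are long, and across all genes, which are not independent, the log2 fold change fell with gene length (Spearman rho = -0.21 in H7 and -0.20 in UNKC tumours). With the length trend removed the median of these 9 was still -1.22 in H7 and -1.39 in UNKC tumours, and 6 and 9 of them stayed called lower. The 9 were chosen for being lower in these same data, so this median cannot decide on length as the cause. Over all 19 members the median was -0.33 and -0.62 without a list call (adjusted p = 0.81 and 0.37). For Kmt2a (-1.34 ± 0.208 before, -0.25 ± 0.217 after), Kmt2d (-1.59 ± 0.247, -0.33 ± 0.257) and Ncoa6 (-0.68 ± 0.162, -0.32 ± 0.146) in H7 tumours the call ended because the fold shrank. Kmt2c kept its call but shrank from -1.77 to -0.66 in H7 and from -2.08 to -0.98 in UNKC tumours. In UNKC tumours Kmt2a shrank from -1.79 to -0.70 and Kmt2d from -2.44 to -1.27. Cxxc1, of 2537 bases, did not shrink (-2.92 to -3.46 in H7, -2.79 to -3.33 in UNKC tumours). Length stays open for the genes that shrank. Ncoa6 in H7 tumours also shrank to -0.50 without H7 replicate 2. With the tumours thinned the medians of the 9 were -2.38 and -2.77. Thinning leaves the normal counts as they were, and the 9 were chosen for being lower against those counts. Low depth of the normal libraries therefore stays open. Genomic DNA is argued against by the 0.195% of the normal reads of the 9 that the read density of olfactory receptor genes would give. A lower level of these genes in tumour cells than in pancreas cells, or a shift of cell types, may also contribute and was not tested.

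Spp1 was higher in UNKC than in H7 tumours. The macrophage and monocyte list did not fall with Spp1, with a median H7 minus UNKC of 0.73 (95% bootstrap interval over its genes -0.07 to 1.23). Its genes were spread, with an interquartile range of 1.63, 5 called lower and 4 higher, and 12 of 23 exceed 5 CPM in normal pancreas. The interval does not cover the spread between samples. More macrophages in UNKC tumours, or a change of state in macrophages, therefore stay open. The fragment counts gave -1.48, and Spp1 had 2 reads per fragment, so the 2 sets of counts held it alike. An error from reads of overlapping genes that both sets share would not show, and stays open. More epithelial cells in UNKC tumours cannot be told apart, since the ductal and epithelial list had a median of -0.57 (95% bootstrap interval over its genes -1.24 to -0.12) with an interquartile range of 1.55. A difference between the lines themselves may also be the source and was not tested.

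Smad4 and Mtap were lower in H7 than in UNKC tumours. The other tested genes starting within 500 kb had a median of -0.21 for 4 genes around Smad4 and -0.069 for 5 around Mtap (1 higher). Around Smad4, Mex3c was called lower in H7 tumours at -0.53, and Mapk4, at 0.0402 and 0.171 CPM, stood at -2.01 without a call (adjusted p = 0.0742). Elac1 and Me2, which lie between Smad4 and Mapk4, at 0.18 and 0.11, argue against a lower segment that carries them. Around Mtap, Cdkn2a (0.255 and 0.136 CPM in H7 and UNKC tumours), Mir31 (0.607 and 0.675) and Cdkn2b (1.52 and 1.59) were low in both. Wincr1 and Klhl9, which start before Mtap, held more reads (8.38 and 185.8 CPM in H7, 9.999 and 98.64 in UNKC tumours). Wincr1 was not called, at -0.26 ± 0.25 (adjusted p = 0.567), and Klhl9 was called higher in H7 tumours, at 0.91. These values argue against a lower segment that carries Wincr1 or Klhl9. A changed segment around Mtap that leaves them out, or one limited to Smad4, stays open. In the fragment counts the smaller difference was -2.19. An error from reads of overlapping genes that both sets of counts share was not tested. For Mtap the difference comes mainly from a rise in UNKC tumours (6.06 against normal pancreas), as H7 tumours were not called against normal pancreas (-0.34, adjusted p = 0.396). They were called lower with the length trend removed (-0.87, adjusted p = 0.0444) and with the tumours thinned (-1.33, adjusted p = 0.0403), and higher when scaled by total counts (2.95), so a fall in H7 stays open. A difference between the lines limited to each gene may remain, and its cause was not tested.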

How the results depend on the processing

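Removing the length trend, thinning the tumours, fragment counts, halved counts, z-scores and leaving ribosomal RNA out were tests chosen only after the data were seen. Of the log2 fold changes of named genes over the alternatives 3038 kept direction and side of the threshold, 9 gained a call, 70 lost one and 13 reversed. Of gene counts 104 stayed within 1.5 times and 28 moved, and of list counts 44 and 7. Scaling by total counts moved the median log2 fold change of all genes from 0.34 to 3.61 in H7 and from 0.42 to 3.77 in UNKC tumours, RLE to 0.17 and 0.21, upper-quartile factors to -0.01 and 0.05, DESeq2 to -0.28 and -0.27, so counts of higher and lower genes against normal pancreas follow the scaling. Total counts gave 12710 higher and 524 lower in H7, 13500 and 312 in UNKC tumours, 648 higher in H7 than in UNKC, 13 and 12 lists against normal pancreas and r = 0.839. They reversed, in H7 tumours, Cxxc1 (0.38), Setd1b (0.65), Kmt2a (1.93), Kmt2d (1.67), Ncoa6 (2.62), Smad4 (2.14) and Mtap (2.95), in UNKC tumours Cxxc1 (0.58) and Setd1b (0.021), and Wdr5 between the tumours (-0.017); by construction they ignore the composition of the libraries. Between the tumours DESeq2 called 2620 genes higher in H7 and 2590 lower, and the fit of only those 4 libraries 2318 and 2497, so the excess of lower genes depends on the fit (38.9% of calls higher as fitted, 50.3% and 48.1% here); the cause was not tested. A test against a fold of 2 left 2775 and 2177, 2627 and 1726, and 343 and 849 genes, since it asks for more. Thinned tumours gave 2353 and 2374 in H7, 2384 higher in UNKC, and 418 and 697 between the tumours, with 7 lists, r = 0.786 and Wdr5 at -0.10, from fewer reads and tested genes. An estimated correlation left 0, 0 and 0 lists (4, 4 and 0 at an unadjusted p under 0.05, while fry called 29, 29 and 3), and the cause was not tested. It also missed the list raised in simulated data (adjusted p = 0.195 and 0.0502), so its losses do not show that a list is unchanged. Camera on z-scores gained macrophage markers in H7 (adjusted p = 0.00487) and UNKC tumours (0.00584), endothelial markers in H7 (0.0493) and osteopontin receptors in UNKC tumours (0.00958). Between the tumours it gained ERK targets (0.00334) and ductal and cell cycle genes (0.0464 each). The calls it lost are named above.

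Leaving out 1 library at a time gave 3581 to 5726 higher and 2600 to 3534 lower genes in H7, 3507 to 5679 and 2183 to 3265 in UNKC tumours, and 184 to 2165 and 378 to 2456 between the tumours. The lowest counts between the tumours came without H7 replicate 1 and the highest without normal replicate 2 (2165) and normal replicate 1 (2456), and the lists ranged from 17 to 23, 15 to 21 and 12 to 18. The correlation ranged from 0.824 (without H7 replicate 2) to 0.920 (without normal replicate 1). Cd274 between the tumours ranged from -0.0026 (without H7 replicate 2) to 0.28 (without H7 replicate 1), and Mtap in H7 tumours from -0.63 (without H7 replicate 2) to 0.00098 (without normal replicate 2); neither extreme was called. Wdr5 gained a call in H7 tumours without normal replicate 1 (0.43) or 2 (1.63), in UNKC tumours without normal replicate 2 (1.57), and in both with total counts (4.11 and 4.13) and in DESeq2 (0.74 and 0.64). With a replicate block 4571 and 3402, 4499 and 2960, and 1174 and 2038 genes were called, and Pdcd1 was not called in H7 (adjusted p = 0.0799) or UNKC tumours (0.0506). Deviations of replicates correlated across genes at r = 0.53 for H7 and UNKC, and at -0.01 and -0.02 with normal pancreas. Replicates 2 of both tumours held the muscle reads. Whether these reads, or another trait that same-numbered tumour samples share, gave the r of 0.53 was not tested. At the depth of the normal libraries, changes of 2-fold against normal pancreas were mostly missed in simulated data (3.19% and 3.55% recovered).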

Other observations

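No test in this part was chosen before the values were seen, except those of the lists and the gene comparisons they rest on.

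Against normal pancreas the chemokine receptor Cx3cr1 rose in H7 tumours and the scavenger receptor Cd163 fell (not called when scaled by total counts, -0.80, adjusted p = 0.088), while the class II and lysosomal genes H2-DMb1 and Ctss rose. UNKC tumours held more Arg1 and Ccl5 than H7 tumours and H7 tumours more Csf3r, Cxcl3 and Isg15. Of these, Arg1, Ccl5 and Isg15 lost their call between the tumours without H7 replicate 1 (adjusted p = 0.057, 0.0838 and 0.0785), and Isg15 also without H7 replicate 2 (0.0894).

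Of mast cell, mesothelial and B cell genes 6 of 9, 5 of 6 and 6 of 16 were called higher in UNKC than in H7 tumours, with Hdc the other way (list medians H7 minus UNKC -3.90, -3.22 and -2.62). The 3 list calls were lost with an estimated correlation (adjusted p = 0.644 each), and the mast cell list lost its call with the length trend removed. Skeletal muscle genes held 47978 reads in H7 replicate 2 and 186858 in UNKC replicate 2, against 732 and 148 in replicates 1.

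Reads of the Y-linked gene Ddx3y were 0 and 0 in H7, 1489 and 192 in UNKC and 0 and 2 in normal pancreas samples, and the sex of the mice is not stated. Lars2 held 685372 and 10416 reads in the normal libraries and from 1903 to 3198 in the tumours.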
